A study of Mus musculus with 6 samples.

How the data were processed

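Mouse aortic vascular smooth muscle cells (VSMCs) of the C57BL/6 strain were kept in a medium with 10% fetal bovine serum and carried an adenovirus for 48 h, per the labels' protocols. Total RNA was freed of ribosomal RNA and turned into stranded libraries, so that both polyadenylated and other transcripts could be read. The labels place 3 libraries in a Myocd knockdown group and 3 in a group given a negative control virus; the series' design text calls the second group wildtype cells. Nothing in the labels says whether the 3 libraries of a group came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical.

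Per the submitters' processing notes, the reads were handled with cutadapt, HISAT2 2.0.4, Cufflinks and Cuffdiff 2.2.1, and the builds mm10 and mm9 are both named without their roles. The annotation release, and whether strand was used in counting, are not given in the sources used here. The authors deposited 1 table of protein-coding genes and 1 table of long noncoding RNA (lncRNA) transcripts. Each holds FPKM values (fragments scaled by transcript length and library size) per library, normalized by the authors, next to a count column per library. The deposited count columns hold estimated counts: in each library nearly all low values were whole multiples of 1 constant, between 0.916 and 1.20, so each column is an estimated fragment number multiplied by a scaling constant. Divided by that constant, 90.1% to 90.4% of the values above 0 in the mRNA table and 70.3% to 71.7% in the lncRNA table lay within 0.01 of a whole number. The other values are fractional, as when fragments are shared out between overlapping transcripts.

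The mRNA table has 22565 rows, and the rows of 79 symbols that occur more than once were summed to give 22482 genes. The lncRNA table has 56348 rows for 31550 distinct transcripts, because a transcript is repeated for each coding transcript it is paired with; the repeated rows hold equal values and each transcript was used once. Coordinates are those of the tables with 1 added to the start. With that shift the start of 6261 genes equals the GRCm38 (mm10) start of the RefSeq gene of that symbol, against 472 genes without it, so coordinates are given as mm10. A locus in the tables can span several overlapping genes and then exceeds the gene itself.

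The depth, as fragments recovered from the mRNA table, was 9117653, 8937947 and 7528155 in the libraries labelled knockdown (replicates 1, 2 and 3) and 9793785, 9304243 and 9303518 in those labelled control. Intervals and limits from these numbers cover counting error only. A chi-square comparison of fragment numbers over genes found every pair of libraries within a group to differ by more than sampling noise, with a chi-square per gene of 2.44 to 6.01, so no library was counted as a copy of another.

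The main test was limma 3.58.1 with an intensity trend (R 4.3.3), on log2(FPKM + 0.1), with group as the only term, since FPKM values are not counts. Genes were kept with at least 0.5 FPKM, and lncRNA transcripts with at least 0.1 FPKM, in at least 3 of the 6 libraries. Where libraries were left out, the number required was the size of the smaller group. P-values were two-sided and adjusted by Benjamini and Hochberg within each table, with a threshold of 0.05. Fold changes on this scale understate the change of low genes. All log2 fold changes are the libraries labelled knockdown minus those labelled control, with the standard error (SE) of the fit, and means are given with their SD over 3 libraries. As alternatives, edgeR 4.0.16 (quasi-likelihood test, TMM scaling) and DESeq2 1.42.0 were run on the recovered fragments rounded to whole numbers. They were not made the main test because the deposited counts are estimated and scaled.

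Gene lists, 34 in number, were fixed before the data were examined and matched by exact symbol. Lists with at least 5 tested members, 28 in all, were compared with all other tested genes by camera with a preset correlation of 0.01 between genes. Camera with an estimated correlation, and fry, which asks only whether a list's own genes move one way, were run beside it. The named genes follow a rule fixed at the same time: Myocd, the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 FPKM in a group and no overlap between the groups (predicted genes left out), and up to 4 members of smallest p in each called list and in 4 lists always described. For lncRNAs the rule took Mir143hg (Carmn), H19, Neat1, Malat1 and Meg3, and the 4 largest rises and falls with a mean of at least 0.5 FPKM in a group. Genes named outside the rule are marked as chosen after their values were seen.

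The alternatives were other pseudocounts, filters and scalings, limma without trend, with robust estimation or with library weights, the replicate number as a block, each library left out in turn, and the count tools. Leaving out both replicate 3 libraries, edgeR with a block, and lncRNA transcripts summed per gene name were chosen after seeing the data, as was the test of KEGG pathways as the mRNA table names them.

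The scripts were tested on simulated data for this design. With 200 of 11476 genes changed, limma recovered 44 of 67 genes changed 1.5-fold, 54 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 6 false calls among 170. For lncRNA transcripts it recovered 0 of 67, 15 of 67 and 45 of 66, with 4 false calls among 64 (edgeR recovered 6, 26 and 57). Both simulations left out rows with few fragments and changed only rows with many. The lncRNA simulation tested 3529 transcripts, against 4955 in the data. Recovery and false calls among transcripts near 0 are therefore not covered. At an unadjusted p under 0.05, the list test called 100 of 100 simulated lists shifted 1.2-fold and 4 of 100 unshifted lists. Their 25 members were drawn at random from all tested genes, so these shares do not cover lists of co-regulated genes. Figures were drawn with matplotlib 3.10.9.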

Results

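RNA was measured in cultured mouse aortic VSMCs, the contractile cells of the vessel wall, 48 h after they received adenovirus, per the labels. The series sets 3 libraries labelled Myocd knockdown against 3 libraries labelled negative control virus. It asks what the transcriptional coactivator myocardin does for the state of these cells. The sample titles read ADV for the libraries labelled knockdown and Ctrl for those labelled control. The design text calls the second group wildtype cells, so whether that group received virus is not certain. If it did not, a response to the virus cannot be told apart from a response to Myocd. Recovered fragments over protein-coding genes ranged from 7528155 to 9793785 per library. In all, 11612 genes and 4955 lncRNA transcripts were expressed highly enough to be tested.

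Myocd, which encodes the coactivator of serum response factor (SRF) that drives smooth muscle genes, ran against the labels. It stood at 131.7, 130.1 and 145.5 FPKM in the 3 libraries labelled knockdown and at 0.0355, 0 and 0.125 FPKM in the 3 labelled control. The means were 135.8 ± 8.49 and 0.0535 ± 0.0644 FPKM (SD, n = 3 each). The recovered fragments were 4984, 4702 and 4466 against 2, 0 and 7, where a count of 0 allows up to 3 fragments. Its log2 fold change was 9.87 (SE 0.27, limma adjusted p = 1.11e-05), and edgeR gave 10.73 (adjusted p = 2.71e-12). The groups did not overlap. An exact two-sided permutation test of this single gene gave p = 0.1, the smallest that 3 against 3 libraries allow. In the tables Myocd (ENSMUSG00000020542) lies on the minus strand of chromosome 11, from 65176561 to 65269989 (mm10). The libraries are therefore called by their labels throughout. Every direction below is that of the libraries labelled knockdown relative to those labelled control, so a gene that rose was higher where Myocd was higher.

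**Figure D1:**
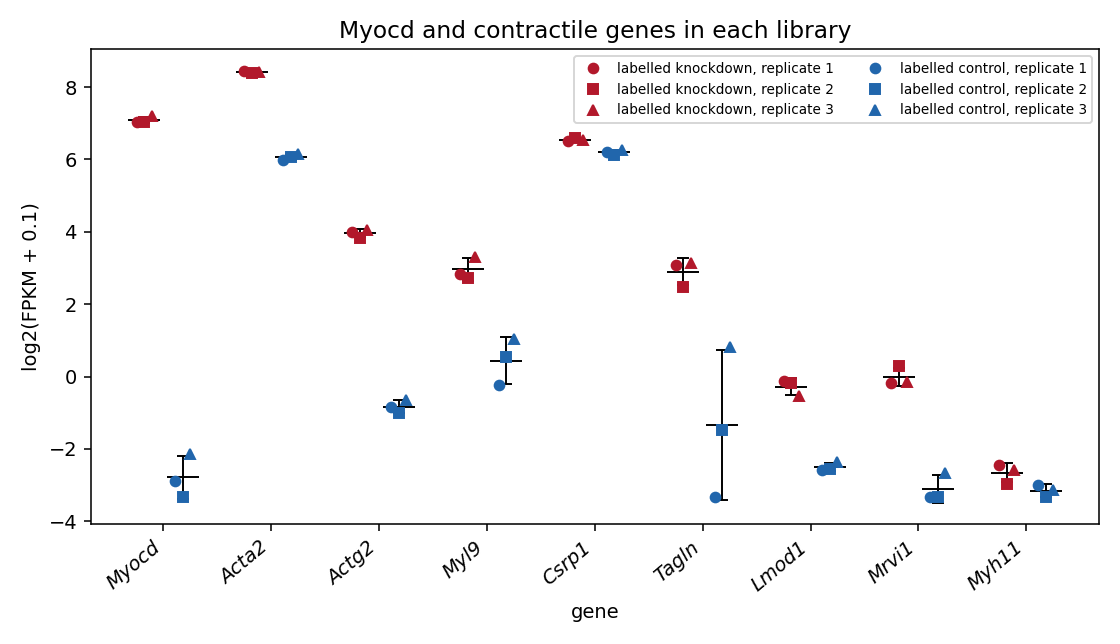
FPKM of Myocd and 8 contractile genes in each library, as log2(FPKM + 0.1); points are libraries (marker shape by replicate, colour by label), horizontal lines are group means and bars are ± 1 SD of the 3 log2 values. Myocd lies between 130.1 and 145.5 FPKM in the libraries labelled knockdown and at or below 0.125 FPKM in those labelled control, and Acta2 and Actg2 separate in the same direction, while Myh11 stays below 0.1 FPKM in all 6.

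Several contractile smooth muscle genes were higher in the libraries labelled knockdown, though most tested members of the list did not pass. Acta2, the smooth muscle alpha-actin, rose 5.06-fold, from 67.2 ± 4.16 to 340.2 ± 7.16 FPKM (log2 fold change 2.34, SE 0.05, adjusted p = 4.40e-06). Actg2, the enteric smooth muscle actin, rose from 0.464 ± 0.0703 to 15.5 ± 1.14 FPKM (log2 4.79, adjusted p = 1.89e-05). Myl9, a regulatory myosin light chain, rose from 1.35 ± 0.605 to 7.80 ± 1.76 FPKM (log2 2.52, adjusted p = 0.0142). The LIM protein gene Csrp1 rose by a smaller step, from 73.3 ± 2.98 to 93.3 ± 2.18 FPKM (adjusted p = 0.0146). Of 26 tested members of the contractile list 9 rose and 17 did not pass. Adjusted over the list alone, 13 rose and 1 fell. Camera placed the list above other genes (adjusted p = 1.41e-07; adjusted p = 0.0919 with an estimated correlation). The other 5 that rose, named after their values were seen, were Mrvi1, Jph2, Synpo2, Lmod1 and Des. Tagln, also chosen after its values were seen, was at 7.52 ± 1.77 against 0.637 ± 0.887 FPKM and did not pass in limma (adjusted p = 0.0556), while edgeR called it (adjusted p = 0.00255). Smtn (56.5 against 57.6 FPKM), Mylk (7.74 against 7.31) and Tpm2 (72.7 against 68.8) did not pass. Myh11, the smooth muscle myosin heavy chain, averaged 0.0604 and 0.0132 FPKM and was too low to test. Acta1, Acta2 and Actg2 are near-identical in sequence, so fragments may be shared out between them.

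Across the transcriptome 400 of 11612 genes passed, 213 of them higher and 187 lower in the libraries labelled knockdown. An unadjusted p under 0.05 was reached by 2603, where chance gives 581. Most changes were small, with a median absolute log2 fold change of 0.39, and 41 called genes (22 higher, 19 lower) changed by at least 1 on the log2 scale. Besides Myocd, and among called genes with a mean of at least 1 FPKM in a group and with predicted genes left out, the largest rises were Acta1 (skeletal alpha-actin, 9.20 ± 1.12 against 0.0720 ± 0.0733 FPKM, log2 5.84), Actg2, Atf7, Myl9, Ifi44l, Ccl5, Acta2 and Vwf. The largest falls were Snurf, Ankrd39, Amigo1, Zfp809, Ttc32, Map2, Dusp12 and Dexi. Ankrd39 fell from 1.75 ± 0.350 to 0.0532 ± 0.0466 FPKM (adjusted p = 0.00969) and the phosphatase gene Dusp12 from 9.95 ± 0.323 to 4.15 ± 0.365 FPKM (adjusted p = 0.00326), both also called by edgeR. Of these 16 genes, edgeR did not call Vwf (adjusted p = 0.0869), Amigo1 (adjusted p = 0.389) or Map2 (adjusted p = 0.697). It did not test Atf7, Ifi44l or Snurf. The recovered fragments gave 1150 calls with edgeR (630 higher, 520 lower) and 717 with DESeq2 (396 and 321). Of the 400, edgeR called 318 in the same direction. Leaving out 1 library lowered the count to 60 (knockdown 1), 60 (knockdown 2), 178 (knockdown 3), 52 (control 1), 44 (control 2) or 165 (control 3). Leaving out both replicate 3 libraries, an alternative added after seeing the data, lowered it to 76.

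The replicate 3 libraries of both groups stood apart from the others. EdgeR called 296 genes between replicate 3 and the other replicates with group in the model, against 0 for replicate 1 and 1 for replicate 2. Limma called 1 gene for replicate 3, 0 for replicate 1 and 0 for replicate 2, with 1588, 438 and 417 at an unadjusted p under 0.05. The fibrillar collagen and elastic fibre list and the heritable aneurysm list were higher in replicate 3 (camera adjusted p = 0.00194 each), as was the contractile list (adjusted p = 0.0157). Acta2 and Actg2 were higher in each of the 3 libraries labelled knockdown than in any labelled control.

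**Figure D2:**
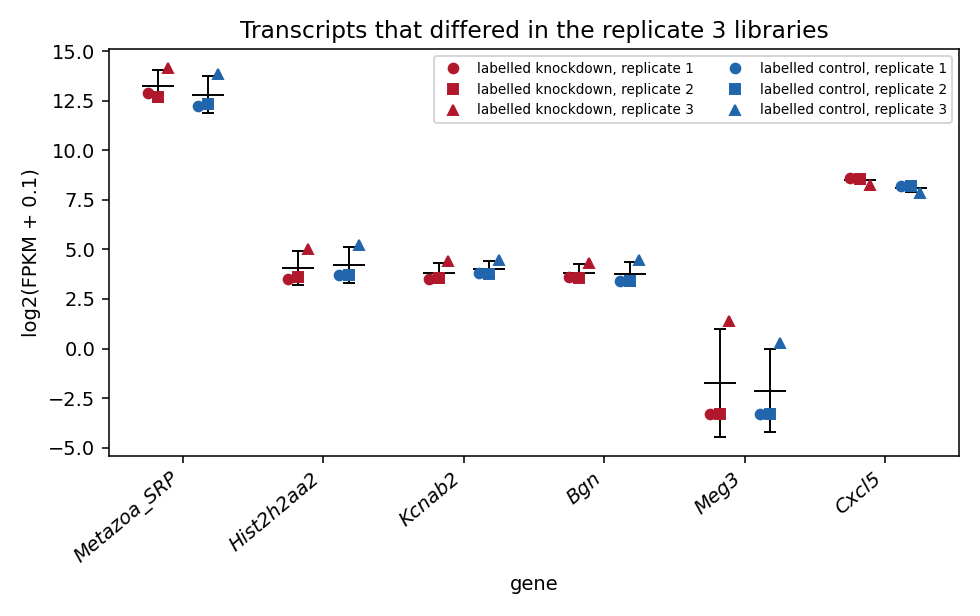
FPKM of 6 genes or RNA families, chosen after their values were seen, that differed in the replicate 3 libraries, as log2(FPKM + 0.1); points are libraries (marker shape by replicate, colour by label), horizontal lines are group means and bars are ± 1 SD of the 3 log2 values. Metazoa_SRP, summed over its transcripts, reaches 18180 and 14850 FPKM in the replicate 3 libraries and at most 7627 FPKM in the others.

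Lists of cytoskeletal genes, matrix proteases and inhibitors, YAP and TEAD targets, modulated cell markers and growth factors were also called upward. In the focal adhesion and actin cytoskeleton list 5 of 29 members rose and 24 did not pass (15 rose and 2 fell adjusted over the list alone). Those that rose included the fibronectin receptor subunit Itga5 (log2 0.34, SE 0.04, adjusted p = 0.0132), vinculin (Vcl, log2 0.30) and non-muscle myosin Myh9 (log2 0.31). The camera adjusted p was 7.78e-06 (adjusted p = 0.0558 with an estimated correlation). Of 22 matrix proteases and inhibitors 6 rose and 16 did not pass (8 rose adjusted over the list alone). Timp3 went from 29.1 ± 0.268 to 42.0 ± 1.76 FPKM, and Mmp19 rose as well. That list reached a camera adjusted p of 4.90e-05 (adjusted p = 0.0645 with an estimated correlation). Targets of YAP and TEAD had 2 of 19 members up, Ctgf (2.34-fold, log2 1.25, SE 0.15, adjusted p = 0.0106) and Ankrd1 (log2 0.44). The other 17 did not pass (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.000702, adjusted p = 0.117 with an estimated correlation). Among markers of modulated, dedifferentiated smooth muscle cells 4 of 18 rose and 14 did not pass (6 rose and 2 fell adjusted over the list alone). Thbs1 went from 134.9 ± 0.931 to 243.7 ± 4.23 FPKM (adjusted p = 6.25e-05), Tnc from 5.01 ± 0.376 to 8.16 ± 0.463 and Lgals3 from 675.9 ± 23.6 to 823.7 ± 18.4, with a camera adjusted p of 0.00255 (adjusted p = 0.0752 with an estimated correlation). Growth factors and receptors had 4 of 32 members up and 28 that did not pass (5 rose adjusted over the list alone), including Igfbp7 and Inhba (log2 0.42 and 0.44; camera adjusted p = 0.000702, adjusted p = 0.0867 with an estimated correlation).

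**Figure D3:**
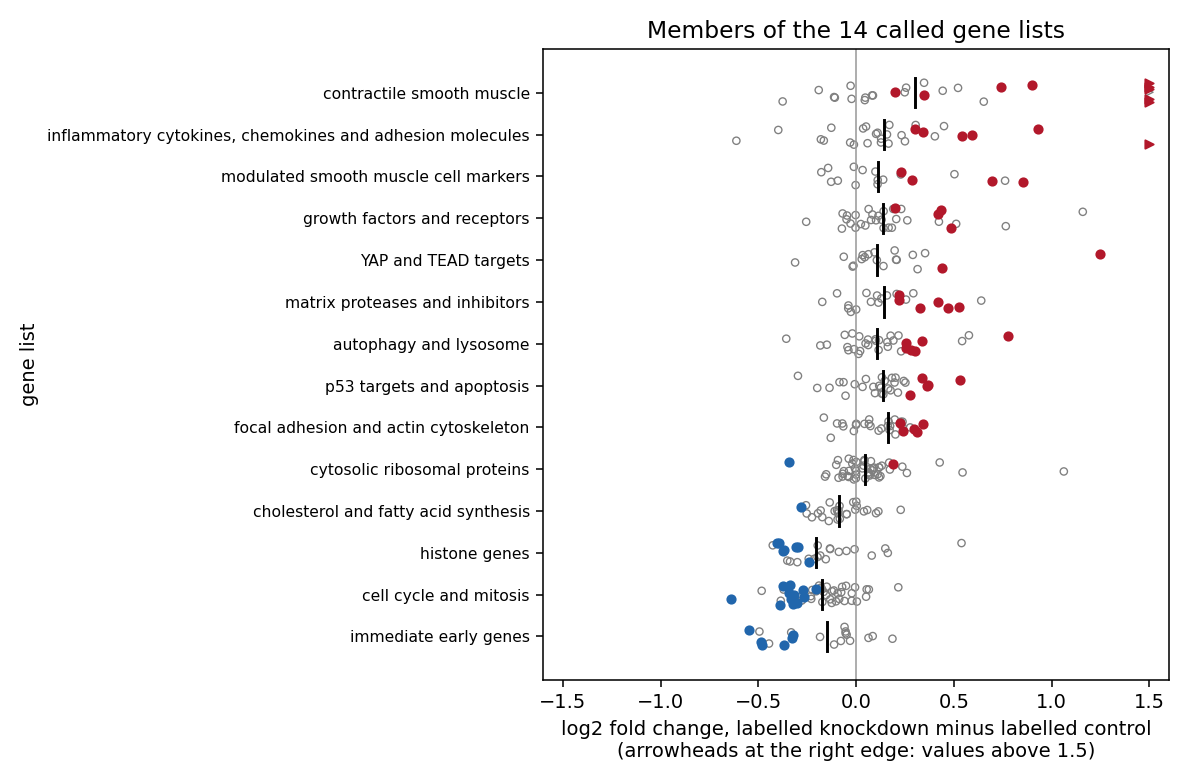
Log2 fold change (libraries labelled knockdown minus labelled control) of every tested member of the 14 lists that camera called with its preset correlation; filled red points rose and filled blue points fell in limma, open points did not pass, black bars are list medians and arrowheads mark values beyond the axis. The contractile list has the highest median, 0.30, and the histone list the lowest, -0.21.

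Lists of inflammatory genes, p53 targets, and autophagy and lysosome genes were also called upward with the preset correlation, though most members did not pass on their own. Of 28 inflammatory cytokines, chemokines and adhesion molecules 6 rose and 22 did not pass (10 rose adjusted over the list alone; camera adjusted p = 7.78e-06, adjusted p = 0.054 with an estimated correlation). The T cell and monocyte chemokine Ccl5 rose 5.10-fold, from 73.9 ± 3.89 to 376.9 ± 39.2 FPKM (log2 2.35, SE 0.08, adjusted p = 2.25e-05). Ccl8 rose from 32.9 ± 3.58 to 62.7 ± 2.25 FPKM, Ccl2 from 213.8 ± 13.6 to 310.8 ± 8.84 and the acute-phase gene Saa3 from 27.6 ± 0.669 to 41.7 ± 2.22. Of 30 p53 targets and apoptosis genes 5 rose and 25 did not pass (5 rose adjusted over the list alone; camera adjusted p = 0.000127, adjusted p = 0.054 with an estimated correlation). They were Ccng1 (log2 0.53, SE 0.05, adjusted p = 0.0082), Mdm2 (0.36), the cell cycle inhibitor Cdkn1a (0.27), Zmat3 (0.37) and Trp53inp1 (0.34), the last chosen after its values were seen. Of 32 autophagy and lysosome genes 6 rose and 26 did not pass (10 rose adjusted over the list alone; camera adjusted p = 9.96e-05, adjusted p = 0.054 with an estimated correlation), for example Map1lc3a (log2 0.78), Gabarap (0.25), Ctsd (0.28) and Lamp1 (0.25).

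Lists of cell cycle, histone and immediate early genes were called downward with the preset correlation, though most members did not pass on their own. Of 48 cell cycle genes 12 fell and 36 did not pass (24 fell adjusted over the list alone; camera adjusted p = 1.24e-10, adjusted p = 0.054 with an estimated correlation). The replication licensing gene Mcm5 fell from 33.2 ± 0.527 to 25.3 ± 0.651 FPKM (log2 -0.39, SE 0.05, adjusted p = 0.0133), Cdc6 from 12.1 ± 0.524 to 7.74 ± 0.711 and the mitotic kinesin Kif20a from 39.8 ± 0.351 to 31.5 ± 0.794. Of 26 histone genes, most of which are transcribed during DNA replication, 7 fell and 19 did not pass (12 fell adjusted over the list alone; camera adjusted p = 7.78e-06, adjusted p = 0.054 with an estimated correlation). Hist1h4d and Hist1h3f fell by 0.41 and 0.37 on the log2 scale, though near-identical copies make single histone genes uncertain. Of 20 immediate early genes, the first transcription factors induced by growth signals and in part SRF targets themselves, 6 fell and 14 did not pass (7 fell adjusted over the list alone). Egr1 fell from 150.0 ± 2.78 to 107.3 ± 0.264 FPKM (log2 -0.48, SE 0.04, adjusted p = 0.00213), Fos from 54.0 ± 0.761 to 38.5 ± 1.74, Ier2 from 55.2 ± 3.89 to 37.7 ± 0.561 and Junb from 120.8 ± 1.80 to 96.5 ± 2.45, with a camera adjusted p of 7.19e-05 (adjusted p = 0.0688 with an estimated correlation).

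Camera also called 2 lists on few members. Of 27 cholesterol and fatty acid synthesis genes 1, Fasn, fell (log2 -0.28, adjusted p = 0.0186) and 26 did not pass (2 fell adjusted over the list alone; camera adjusted p = 0.0359, adjusted p = 0.13 with an estimated correlation). Among 50 cytosolic ribosomal proteins Rps19 rose (log2 0.19), Rpl34 fell (log2 -0.34) and 48 did not pass (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0331 upward, adjusted p = 0.0973 with an estimated correlation). Both calls ended on edgeR fits (adjusted p = 0.0615 for cholesterol and 0.0639 for ribosomal proteins) and without the trend (adjusted p = 0.0779 each). The cholesterol call was lost in 8 of 20 other settings, among them without knockdown 3 (adjusted p = 0.105), control 1 (0.0662) or control 2 (0.0525), over a range from 0.0223 to 0.13. The ribosomal call was lost in 5, among them quantile normalization (adjusted p = 0.512) and no filter (0.0551), over a range from 0.0126 to 0.512.

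In all, 14 of the 28 tested lists passed with the preset correlation, 10 upward and 4 downward. With an estimated correlation camera called 0, with 12 lists at an unadjusted p under 0.05 and a lowest adjusted p of 0.054. The estimate was above the preset 0.01 for some called lists, such as the contractile list (0.131). It was below 0.01 for others that also lost their calls, such as the histone (-0.024), p53 (-0.006) and autophagy (-0.007) lists. A larger correlation therefore does not account for every loss, and the cause was not tested. EdgeR fits gave 15 of 27 lists and fry 16. With the preset correlation, camera called as many as 9 lists on other splits of the 6 libraries into groups of 3.

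Lists tied to the study's aneurysm question, and several others, were not called. Of 26 heritable aortic aneurysm and dissection genes Acta2 and filamin A (Flna, 263.3 ± 3.22 to 311.1 ± 16.7 FPKM) rose and 24 did not pass, with the same count adjusted over the list alone (camera adjusted p = 0.313). Mat2a (55.5 against 65.3 FPKM, adjusted p = 0.107) and Tgfb3 (13.4 against 15.5, adjusted p = 0.187) had the next smallest p. Among 19 SRF cofactors and regulators of smooth muscle identity Myocd itself and Prrx1 (log2 0.32, adjusted p = 0.0337) rose, also adjusted over the list alone. Mef2c (2.87 against 3.95 FPKM, adjusted p = 0.146) and Mkl2 (13.8 against 8.52, adjusted p = 0.148; lower in edgeR, log2 -0.13) were among 17 that did not pass (camera adjusted p = 0.326). Fibrillar collagens and elastic fibre components had 1 of 31 members up (3 up and 1 down adjusted over the list alone; camera adjusted p = 0.246), and the TGF-beta list 3 of 27 (3 up and 1 down adjusted over the list alone; adjusted p = 0.333). EdgeR on fragments called the SRF cofactor list (adjusted p = 5.98e-11), which holds Myocd itself and had a median log2 fold change of 0.004 there, and the aneurysm (adjusted p = 0.000548) and TGF-beta lists (adjusted p = 0.0145). Of 20 other settings of camera that was the only 1 to call the SRF cofactor and TGF-beta lists, which fry also called (adjusted p = 0.0311 and 0.00855). Without control 3 camera also called the aneurysm list (adjusted p = 0.0379) and the fibrillar collagen and elastic fibre list (adjusted p = 0.0483). Interferon-stimulated genes moved both ways, with 5 of 35 higher (Rsad2, Zbp1, Irf7, Oasl1 and Gbp2) and 3 lower, including Ifit3 and Oas1a, these 7 named after their values were seen (5 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.823). Rsad2 was at 18.9 ± 0.709 against 8.78 ± 1.06 FPKM (adjusted p = 0.00503).

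The remaining lists were not called either. The unfolded protein response list had 1 of 29 members up and 1 down (4 and 5 adjusted over the list alone; adjusted p = 0.281), oxidative phosphorylation 1 of 43 up and 1 down (4 and 2; adjusted p = 0.373), glycolysis and hypoxia 1 of 29 down (4 up and 2 down; adjusted p = 0.35), and oxidative stress response 1 of 25 down (2 down; adjusted p = 0.745). Of 6 cardiac muscle genes Ankrd1 rose and 5 did not pass, all 5 with negative log2 fold changes (list median -0.23; 1 up and 1 down adjusted over the list alone; adjusted p = 0.799). That median was 0.18 with no filter. Limma called 0 of 16 ion channel and vasoactive receptor genes (2 at an unadjusted p under 0.05, 2 called higher by edgeR; camera adjusted p = 0.727). It called 0 of 5 chondrogenic and osteogenic genes (2 at an unadjusted p under 0.05, 0 called by edgeR; camera adjusted p = 0.939). Neither list gained a call adjusted over the list alone. The median, mean and test differed in sign for the interferon, unfolded protein response, ion channel and chondrogenic lists.

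Markers of other cell types were measured alongside. Limma called 0 of 12 fibroblast markers (5 at an unadjusted p under 0.05, 0 adjusted over the list alone; camera adjusted p = 0.572). EdgeR called 1 of them lower, Cd34 (adjusted p = 0.0357, named after its values were seen). Ly6c1, Gsn and Serpinf1, the highest of the 20 listed fibroblast markers, were at 302.2, 295.9 and 289.8 FPKM over all 6 libraries. Of the 20, 12 were at 1 FPKM or more (median of the 20, 2.01 FPKM). Of 6 pericyte markers limma called 0 (1 at an unadjusted p under 0.05, 1 higher adjusted over the list alone, 0 called by edgeR, camera adjusted p = 0.548). The other marker lists had 3 tested members each. Endothelial Vwf rose, from 0.185 ± 0.107 to 1.24 ± 0.330 FPKM (adjusted p = 0.0346), and was the 1 endothelial call also adjusted over the list alone. Limma called 0 macrophage markers (1 at an unadjusted p under 0.05; Cd14, 17.2 against 20.8 FPKM, fell adjusted over the list alone), and 0 adipocyte, mesothelial or neural markers, which had 1, 1 and 0 members at an unadjusted p under 0.05. EdgeR called 1 of these, the adipocyte gene Plin4 (adjusted p = 0.0462). Krt19 (243.7 FPKM) and Msln (78.0 FPKM), markers of mesothelium, were abundant in both groups and did not pass. They were the only 2 of the 14 listed mesothelial and epithelial markers at 1 FPKM or more (median of the 14, 0.1155 FPKM).

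Long noncoding RNAs were tested per transcript in their own table, where 211 of 4955 passed, 110 higher and 101 lower, with 803 at an unadjusted p under 0.05 against 248 by chance. These calls depended on the processing: edgeR on recovered fragments called 1 of 2322 transcripts and DESeq2 80, though edgeR did not test 158 of the 211. Leaving out 1 library gave 149 (knockdown 1), 10 (knockdown 2), 298 (knockdown 3), 110 (control 1), 119 (control 2) or 153 (control 3). Of these, in the same order, only 86, 7, 146, 70, 67 and 90 were among the 211. The share of higher transcripts in these runs was 62.4%, 60% and 71.1% without knockdown 1, 2 and 3. It was 28.2%, 32.8% and 28.1% without control 1, 2 and 3. The balance of directions thus turned between these runs, which also tested more transcripts (5668 to 5724). The transcript called by edgeR as well was 1 of 3 listed for 2410006H16Rik (chromosome 11, 62602877 to 62604807, plus strand, 462 bases), at 118.1 ± 7.67 against 0.260 ± 0.0145 FPKM (log2 8.36, SE 0.12, adjusted p = 2.4e-06). Summed per gene name, an alternative added after seeing the data, the 3 transcripts were at 259.7 ± 18.1 and 245.1 ± 22.8 FPKM (adjusted p = 0.725). Of the 211 transcripts, 60 overlap an exon of a coding gene on the same strand, where fragments of both cannot be told apart.

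The other large changes were mostly of transcripts near 0 in 1 group. AK215297 (inside Zmynd11) was listed at 0 in all 3 libraries labelled control and at 10.1, 9.90 and 59.0 FPKM in the others. The transcript uc009nxl.1 (Ttc13) and DQ713317 were listed at 0 in the libraries labelled knockdown and at 3.27 ± 0.501 and 2.75 ± 0.466 FPKM in those labelled control. A short Snhg6 transcript, the transcript named Hyi, AK193543 and AK019367 were the others of the 8. EdgeR did not test 6 of these 8 (AK215297, Snhg6, AK193543, AK019367, Ttc13 and DQ713317), which had too few fragments, and did not call Hyi (adjusted p = 0.0917). Summed over all their transcripts Neat1 (237.1 against 226.1 FPKM), Malat1 (5132 against 4972), Mir143hg, the host of the smooth muscle microRNAs miR-143 and miR-145 (6.01 ± 1.01 against 4.63 ± 0.389, adjusted p = 0.365), and H19 (0.922 against 1.25) did not pass. On its own, 1 Malat1 transcript fell in limma (log2 -1.08, adjusted p = 0.0278) and DESeq2 (adjusted p = 9.93e-06) but was not called in edgeR (adjusted p = 0.0997). In limma that call was lost without knockdown 1 (adjusted p = 0.0848), knockdown 2 (0.0975), control 1 (0.0867), control 2 (0.0939) or control 3 (0.0847), and over all settings its adjusted p reached 0.121. Another Malat1 transcript was higher, at 654 ± 229 against 208 ± 216 FPKM (log2 2.10), and did not pass in limma (adjusted p = 0.228). It passed in limma without control 3 (adjusted p = 0.0362) and without both replicate 3 libraries (adjusted p = 0.0373). Of 92 tested transcripts from 25 genes of the named lncRNA list, 1 rose and 3 fell, also adjusted over the list alone.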

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

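Among the results below, the settings that left out both replicate 3 libraries, edgeR with the replicate number, and transcripts summed per gene name were chosen after seeing the data. The cause of these differences was not tested unless one is named. Myocd kept its direction and stayed past the threshold in all 20 other settings, with log2 fold changes from 7.02 (pseudocount 1) to 11.75 (pseudocount 0.01). The 400 called genes became 144 without the trend, 624 with library weights, 1150 with edgeR, 717 with DESeq2 and 76 without both replicate 3 libraries, of which 62 were among the 400. A log2 fold change of at least 1 leaves 41 by construction. Without 1 library the count ranged from 44 (control 2) to 178 (knockdown 3), where fewer libraries also mean less power. Of the called genes 213 of 400 were higher; that share was 53.3%, 48.3% and 50.6% without knockdown 1, 2 and 3, 67.3%, 70.5% and 63% without control 1, 2 and 3, 49.2% with library weights and 52.6% to 56.3% under the other scalings. Other pseudocounts, filters, scalings and robust estimation gave between 355 and 408 genes.

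The 211 called lncRNA transcripts became 79 with pseudocount 1, 90 with no filter, 62 with the stricter filter, 1 with edgeR, 80 with DESeq2, 349 without both replicate 3 libraries and 139 when summed per gene name. Of the 349, 123 were among the 211. Without 1 library the count of called transcripts ranged from 10 (knockdown 2) to 298 (knockdown 3). The gene lists called numbered 12 to 16 in the other limma, edgeR and fry settings and 0 with an estimated correlation; the list test was not run on DESeq2 fits. Of the 74 named genes besides Myocd 63 were called, and of these 47 lost the call when some 1 library was left out and 45 under some other setting. Of 20 named lncRNA transcripts 9 were called, and 5 and 8 of these lost the call. No called gene or transcript among them changed direction.

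Some that did not pass changed direction, again without passing. Mkl2 (log2 0.66 in limma) was at -0.133 in edgeR, -0.135 in DESeq2 and -0.132 in edgeR with the block, and Axl (0.20) at -0.03, -0.032 and -0.03. With quantile normalization 2 Malat1 transcripts went to -0.103 and -0.183. Without 1 library the first of these ranged from -0.037 (knockdown 3) to 0.18 (knockdown 1), a Neat1 transcript from -0.045 (control 3) to 0.035 (knockdown 3), an H19 transcript from -1.684 (control 2) to 0.451 (knockdown 1) and a Mir143hg transcript from -0.654 (knockdown 2) to 0.144 (knockdown 1). Camera turned the direction of 3 lists that were not called, whose medians were then: cardiac muscle 0.183 (no filter), -0.059 (edgeR), -0.049 (edgeR with the block) and, without 1 library, -0.258 (control 1) to -0.062 (control 2, the 1 that turned it); chondrogenic 0.024 (no filter), -0.044 (without the trend), 0.043 (without both replicate 3 libraries), 0 (without knockdown 3), -0.08 (without control 1) and -0.051 (without control 2); interferon -0.034 (without knockdown 3, the 1 that turned it) to 0.01 (without knockdown 2).

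Same-numbered libraries did not deviate together throughout (correlations of 0.037, -0.004 and 0.1 across 11612 genes), and not every library correlated best with its own number, so the replicate numbers were not taken to pair the libraries. With the replicate block limma called 243 genes, 195 of them among the 400, and 1 lncRNA transcript, and edgeR with that block called 1717 genes. The lists called under the limma block numbered 14.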

Other observations

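The KEGG pathway names in the mRNA table, tested by camera only after the data had been seen, gave 268 pathways with at least 10 tested genes, of which 6 were higher and 7 lower in the libraries labelled knockdown. With an estimated correlation camera called 0 of the 268 (20 at an unadjusted p under 0.05, lowest adjusted p = 0.528). Each call below was thus made only with the preset correlation. Lysosome was the leading rise, with 9 of 105 genes up (adjusted p = 0.00178, 0.528 with an estimated correlation), among them Npc2, which exports cholesterol from lysosomes (164.1 ± 3.88 to 216.0 ± 4.88 FPKM), and Ppt1 (38.5 ± 1.32 to 49.6 ± 1.45). Cytokine receptor interaction (8 of 93 up, adjusted p = 0.00287) added Eda2r, Il13ra1 and Ppbp to the chemokines. Complement and coagulation (5 of 28 up, adjusted p = 0.0131) added Cfb (25.9 ± 1.49 to 36.0 ± 1.60) and Masp1. Antigen processing (5 of 41 up, adjusted p = 0.0356) included B2m (546.1 ± 21.2 to 698.8 ± 8.70), Psme1 and Tapbp. Malaria (3 of 25 up, adjusted p = 0.0304) and Focal adhesion (11 of 150 up, adjusted p = 0.037) held Thbs1.

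The leading falls, also lost with an estimated correlation (adjusted p = 0.528), were DNA replication (6 of 35 genes down, adjusted p = 0.00287), with the polymerase subunit Pold1 at 16.8 ± 1.08 against 27.2 ± 2.08 FPKM, mismatch repair (3 of 22, adjusted p = 0.0131), and the histone-rich sets named for systemic lupus erythematosus (10 of 86, adjusted p = 0.00731) and alcoholism (11 of 135 down and 1 up, adjusted p = 0.0356). Aminoacyl-tRNA biosynthesis had 4 of 43 genes down, including Fars2 (9.06 ± 0.516 to 4.28 ± 0.722) and Vars, and 1 up, Lars2 (adjusted p = 0.0244). Selenocompound metabolism (1 of 13 down, adjusted p = 0.0304) and homologous recombination (2 of 27 down, adjusted p = 0.0403) were the others.

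The tests in the paragraphs that follow were chosen only after the results they bear on were seen, except the counts over splits of the libraries. The first pattern is Myocd at 0.0394% of its level in the libraries labelled knockdown when measured in those labelled control. A lowered Myocd transcript in the libraries labelled knockdown is excluded by the log2 fold change of 9.87 (SE 0.27). Exchanged labels and a virus that carried Myocd cannot be told apart here: 9 contractile genes passed as higher where Myocd was high, which both predict, and the virus is the group. Whether the Myocd fragments come from a viral insert or the chromosome needs reads, which were not used here. A biological rise of the endogenous gene is untested.

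The second pattern is that the replicate 3 libraries of both groups share differences from the others. The lncRNA Meg3 was listed at 0 in replicates 1 and 2 of both groups and at 2.52 and 1.11 FPKM in replicate 3, and the signal recognition particle RNA family Metazoa_SRP was at 18180 and 14850 against at most 7627 (these genes were picked for the difference). Lower depth is argued against for control 3, which had 100% of the fragments of control 2, and stays open for knockdown 3, the shallowest of the 6 libraries, which had 84.2% of those of knockdown 2. Fibroblasts in these libraries stay open, since their list, 12 of whose 20 members passed the expression filter in these cultures, gave an adjusted p of 0.34 in camera. A shared culture, batch or handling may also account for it, but the 296 genes that edgeR called (limma called 1) restate the pattern and the labels name no batch, so it cannot be told apart from other sources.

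The third pattern is the 82 genes called on FPKM and not by edgeR on fragments, such as Amigo1 and Map2. EdgeR did not test 9 of the 82, so no disagreement was measured for those 9. Across the 82 the ratio of fragments to FPKM shifted between the groups by a median of 0.3 (log2). The tested genes were picked by their very disagreement, so the shift describes the pattern and decides nothing. In this set the median absolute log2 fold change was 0.51 on FPKM and 0.19 on fragments. A shift in the transcript length behind the FPKM, as when fragments are assigned to other isoforms in 1 group, may account for calls of this kind and stays open, since no transcript lengths were used here. No biological explanation was tested.

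The 6 libraries split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 400 genes (highest other 1), 211 lncRNA transcripts (highest other 2) and 14 lists (highest other 9).

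Rn45s, the ribosomal RNA precursor transcript, was at 8319, 8137 and 7295 FPKM in the libraries labelled knockdown and 10520, 10410 and 8909 in those labelled control.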
